A study of Mus musculus with 5 samples.

How the data were processed

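The series holds 5 single-cell RNA-seq libraries of mouse tissue made with a 10x Genomics droplet kit, in which each RNA molecule is tagged with a unique molecular identifier (UMI) near its 3′ end before amplification. Per the labels, 3 libraries came from liver and 2 from aorta. The liver libraries are labelled DKO on an ApoE background, WT on an ApoE background, and WT with no background named. The aorta libraries are labelled DKO and WT, both on an ApoE background. Each group has 1 library. The labels' protocol mentions 3 mice without saying how they relate to the libraries, and gives an isolation procedure for liver only.

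Per the submitters' processing notes, reads were processed with Cell Ranger 7.1.0 against the mouse build mm10. The authors deposited a table of raw UMI counts per gene and cell for each of 3 data sets (liver on the ApoE background, aorta, and liver without it), each with a table of metadata per cell. The deposited counts were whole numbers, and their sum in each cell equalled the UMI total that the authors' metadata list for that cell. How the authors filtered cells is not given in the sources used here. In the values, no cell had fewer than 499 UMIs, the number of detected genes ran from 201 to 2499 per cell, and the highest mitochondrial share of a cell's UMIs was 20.0 percent in the liver tables and 5.00 percent in the aorta table, per the deposited metadata. An upper bound on detected genes removes the deepest cells, and a bound on mitochondrial share removes cells rich in mitochondrial RNA, so both limit what the levels here describe. The libraries compared on the ApoE background hold equal numbers of cells, 4331 in each liver library and 2800 in each aorta library. Cell types, subtypes and cluster numbers were taken from the authors' metadata, whose column names are those of Seurat and refer to integrated data; how types were named is not given in the sources used here. In each of the 3 metadata tables, 24 other columns were not used.

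The groups were the 5 labels, and 3 comparisons were made: liver labelled DKO against liver labelled WT on the ApoE background, liver labelled WT on the ApoE background against liver labelled WT without it, and aorta labelled DKO against aorta labelled WT. With 1 library per group there is no test, p-value or count of changed genes, and no difference has a replicate check. UMIs were summed over the cells of a class or cluster and given as CPM, the count per 10⁶ UMIs of that class, with an exact Poisson interval. A ratio is the CPM of the first-named library over that of the second, with an exact conditional binomial interval. Shares of cells are percentages of all cells in a library with exact Clopper-Pearson intervals. All intervals are at 95%, and all cover counting error only. They leave out differences between cells of a class, animals, dissociations and library preparations. Where one library had no UMI of a gene, the fold was set against a floor of 3 counts. CPM sums to a fixed total in each class, so genes that take many UMIs lower the CPM of all others.

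A class was compared as a whole only where no cluster of it had more marker genes of another class than of its own among its 10 leading genes. Leading genes were those with at least 200 CPM in the cluster and at least 2 times the CPM of the other clusters after adding 20 CPM to both, ranked by that fold. The hepatocyte class of the ApoE liver table was formed by clusters 0 to 8, 13 and 16. The marker lists hold no pancreatic acinar genes, so cluster 16, which such genes lead and which has no hepatocyte marker among its leading genes, stayed in. Clusters 14 (led by erythroid genes) and 18 (led by cholangiocyte genes), which the authors also call hepatocytes, were kept out; they hold 121 and 8 cells of the library labelled DKO and 16 and 3 of that labelled WT. In the liver table without the ApoE background, the same rule kept out clusters 0 and 2, with 244 and 111 of its 616 cells. Clusters 3, 4, 8 and 12 were used. The authors call every cell of that table a hepatocyte, and no cluster of it had a hepatocyte marker among its leading genes. Any 1 marker of another class thus kept a cluster out. For cluster 0 it was Spp1, a cholangiocyte marker, while Alb stood at 39831 CPM there and at 39838.5 CPM in cluster 3. The smooth muscle class of the aorta was formed by the authors' clusters VS1, VS2 and VS3. All other cells were compared by the authors' cluster, and only clusters with at least 50 cells in both libraries were compared. Genes that led a cluster are not given as results of that cluster.

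The gene lists, the marker genes of cell types and the rule for named genes were fixed before the data were examined. The rule took genes with at least 100 summed UMIs in a class and ranked them by the bound of the ratio interval nearest to 1. It named the 10 highest and the 10 lowest in a main class (hepatocytes in liver, smooth muscle in aorta), up to 4 of each in any other class described, and up to 4 members of each list described, by the same rank. The ranking skipped mitochondrial, ribosomal protein, predicted (Gm and digits), Rik, haemoglobin, immunoglobulin and T cell receptor genes, Xist, Tsix and Y-linked genes, and genes over 10 times higher in another class of the same libraries, which free RNA can bring. Epn1, Epn2, Epn3, Apoe, Hnf4a and Alb were named besides. Some genes that the rule names are not reported here. A list's value is the median log2 ratio over its members with at least 20 summed UMIs in the class, given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. Chosen after the data were seen were the limits for leading genes, the clusters described beyond the main classes, the lists described for each of them, and the use of hepatocyte clusters 5, 7 and 8 as a separate set. Gm42418 and the haemoglobin gene Hbb-bs, which the ranking skips, are given as facts about the libraries and were also chosen after their values were seen.

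Calculations were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0 and igraph 0.11.9, and plots with matplotlib 3.10.9. The ratio intervals and list percentiles were tested on simulated data, with UMIs drawn for the real genes and 200 of them changed by known factors. Summed UMIs were drawn as independent Poisson counts, the model that the intervals assume, so coverage near 95% was built in. The draws hold no variation between cells, so they check the calculation and not how well the intervals suit the real counts. For the liver DKO comparison (8294 genes), 95.6% of intervals held the true ratio, and the interval left out 1 for 100% of genes doubled and 97.7% of genes halved. The corresponding values were 95.8%, 86% and 77.3% for the liver background comparison (6880 genes) and 95.9%, 100% and 95.5% for the aorta comparison (4331 genes). A simulated list of doubled genes reached percentile 100 in each of the 3, and a list of unchanged genes lay at percentiles 7.34, 94.9 and 39.0.

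The alternatives tried were totals without mitochondrial and ribosomal protein genes, ratios shifted so that the median gene is at 0, the mean of each cell's own CPM in place of sums, cells thinned to 1000 UMIs (cells with fewer left out), a stricter filter on cells (at least 500 genes and under 20% mitochondrial UMIs), totals without genes over 10 times higher in another class, other minimum counts for list members, all cells of a library, and clusters made here with the Leiden method at resolution 0.5 (2000 variable genes, 30 components, 15 neighbours) and named from the fixed markers. For gene and list values, the gene limit fell where a share under 0.5 of a library's cells in a class had 500 genes. It was then 0.5 times the median of those cells, so the limit could differ between libraries. In Kupffer cells, 162 of 162 cells labelled DKO and 74 of 79 labelled WT stayed. The mitochondrial limit removed no cell. Other sets of clusters for each main class were added after the data were seen. So were totals without 8 genes linked to ribosomal RNA (Gm42418, AY036118, Cmss1, Cdk8, Lars2, Camk1d and Gphn among them). A doublet caller, scrublet as run in scanpy per library, marked 2 cells of the liver library labelled DKO and none of the other 3 libraries on the ApoE background, under the 0.5% set as the least for a working call, so doublets were not removed. Empty droplets were not used here, so free RNA was not subtracted. The liver libraries on the ApoE background and the one without it lie in separate tables, and only genes in both tables entered their comparison. Gene positions are those of the mouse reference annotation on mm10, the build named in the processing notes.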

Results

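Single-cell RNA was counted in 5 mouse libraries, 3 from liver and 2 from aorta. One liver library and one aorta library are labelled DKO on an ApoE background, and the labels speak of liver DKO mice without spelling the abbreviation out. Another pair is labelled WT on the same background, and the remaining liver library is labelled WT with no background named. The series title concerns liver epsins, which are endocytic adaptors that bind clathrin and ubiquitinated cargo, and their part in dyslipidemia. The tables hold 10999072 UMIs in 4331 cells of the liver library labelled DKO (median 1636 UMIs per cell). There are 9497896 in 4331 cells of the one labelled WT (median 1552). The aorta libraries hold 6228458 UMIs in 2800 cells labelled DKO (median 1774) and 6383082 in 2800 cells labelled WT (median 1709.5). The liver library without the ApoE background has 1883798 UMIs in 616 cells (median 2772). Each group is 1 library, so no difference has a replicate check, and the 95% intervals in brackets cover counting error only. Ratios are CPM in the library labelled DKO over CPM in that labelled WT unless another pair is named.

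Neither Epn1 nor Epn2 was lower in the liver library labelled DKO, so these counts do not bear out its label. In the hepatocyte class, Epn1 (chromosome 7, 5080235 to 5098178 on mm10) had 655 against 518 UMIs, or 71.2 against 58.9 CPM. The ratio was 1.21 (1.07 to 1.36). Epn2 (chromosome 11, 61517249 to 61579687) had 80 against 67 UMIs, a ratio of 1.14 (0.814 to 1.60). Over all liver cells the ratio of Epn1 was 1.18 (1.06 to 1.32) and that of Epn2 1.28 (0.952 to 1.74). In cells outside the hepatocyte clusters they were 1.32 (0.848 to 2.12) and 1.68 (0.758 to 4.22). The deleted exons are not given in the sources used here, and a 3′ tag outside the deleted part of a gene checks nothing. In aortic smooth muscle, where the labels name no deletion, Epn1 stood at 0.965 (0.603 to 1.56) and Epn2 at 1.31 (1.05 to 1.64). Epn3 is not among the genes of the ApoE liver table and had 0 against 2 UMIs over all aorta cells. All directions below are therefore given between libraries labelled DKO and WT, not between genotypes.

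Apoe, which encodes a ligand of lipoprotein receptors and is normally among the abundant transcripts of hepatocytes, was low in all 3 liver libraries, that without a named ApoE background included. Its level in hepatocytes was 32.6 CPM (29.0 to 36.5) in the library labelled DKO and 36.2 CPM (32.3 to 40.4) in that labelled WT on the ApoE background, against 68.8 CPM (52.8 to 88.2) without it. In the same order, Apoc1, an apolipoprotein gene near it, stood at 9147, 8678 and 9531 CPM. These counts do not show a difference in ApoE genotype between the 2 livers labelled WT, so their comparison, too, is one between labels, and "without the ApoE background" means a label that names none. Over all aorta cells Apoe had 29 against 36 UMIs, a ratio of 0.826 (0.488 to 1.38). Xist, transcribed from the inactive X chromosome of females, was present in every library. Over all cells it stood at 645 against 630.5 CPM in liver, 619 against 689.8 CPM in aorta and 441 CPM in the liver without the ApoE background.

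Lymphocytes took a larger part of the liver library labelled DKO, and hepatocytes a smaller one. T cells were 8.91% (8.08 to 9.80) of the cells labelled DKO and 1.99% (1.59 to 2.45) of those labelled WT, a ratio of 4.49 (3.54 to 5.74). B cells of cluster 11 numbered 271 against 31, a ratio of 8.74 (6.02 to 13.1). The authors' B cell cluster led by plasma cell genes had 14 against 21. Neutrophils were 1.18% against 0.393% (ratio 3.00, 1.70 to 5.54). Kupffer cells, the resident macrophages of the liver, were 3.74% against 1.82% (ratio 2.05, 1.56 to 2.72). The share of endothelial cells, 1.501% against 1.32%, had a ratio whose interval includes 1 (1.14, 0.787 to 1.66). The hepatocyte class held 75.1% of the cells labelled DKO and 92.8% of those labelled WT. Cluster 14, led by haemoglobin genes, had 121 against 16 cells. Over all cells the haemoglobin transcript Hbb-bs stood at 3321 against 293 CPM. Among cells with at least 500 genes and under 20% mitochondrial UMIs the Kupffer ratio was 1.32 (0.949 to 1.85), an interval that includes 1, and that of the haemoglobin-led cluster 0.636 (0.171 to 2.04) in place of 7.56. The hepatocyte ratio moved from 0.809 to 0.227 when cells were clustered anew. New clusters with 798, 1192 and 530 cells labelled DKO, and 382, 33 and 348 labelled WT, took names of other types there. Their marker scores were only 0.129, 0.00342 and 0.0224. Those named hepatocytes held 555, 74 and 120 cells labelled DKO and 124, 686 and 2485 labelled WT. Several new clusters thus came mostly from the library labelled DKO or mostly from that labelled WT, which limits comparisons of the hepatocyte class.

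**Figure D1:**
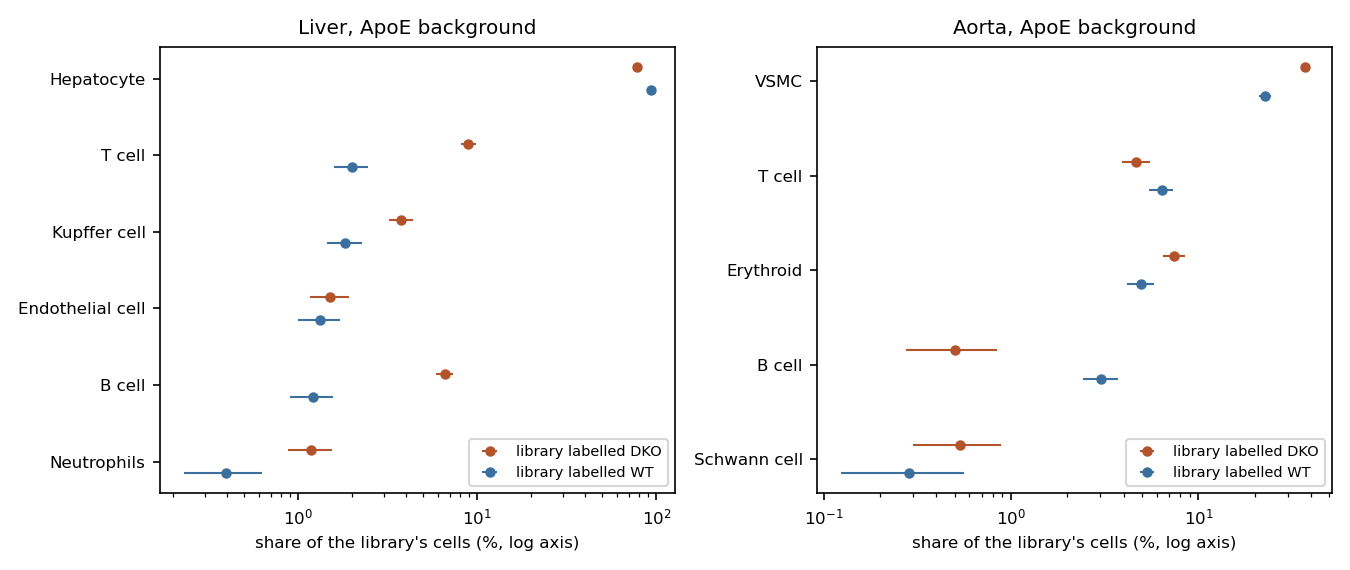
Share of cells in the authors' classes compared by size (percent of all cells of a library, log axis) for the libraries labelled DKO and WT of liver (4331 cells each) and aorta (2800 cells each); points are shares and bars exact 95% Clopper-Pearson intervals, which cover counting error only. In liver, T cells lie at 8.91% against 1.99% and B cells at 6.58% against 1.20%, whereas aortic B cells number 14 against 85. The authors' liver B cells include the cluster led by plasma cell genes, and their hepatocytes include clusters 14 and 18, which the text keeps apart. Aortic fibroblast, stem cell, adipocyte, endothelial and macrophage classes are not drawn.

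The question the title raises for hepatocytes is how genes of lipoprotein uptake and lipid synthesis stood in the 2 libraries. UMIs measure RNA and say nothing of protein levels or turnover. The hepatocyte class held 3253 against 4021 cells. Lipoprotein receptors and their regulators were modestly higher as a group in the library labelled DKO. In the class as a whole, mitochondrially encoded transcripts were higher and nuclear genes of oxidative phosphorylation lower. Both differences were smaller in clusters 5, 7 and 8, which have the most UMIs per cell. Genes of lipid synthesis and apolipoproteins differed little as groups, while single genes such as Apoa4 and Mup9 stood apart.

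Among lipoprotein receptors and their regulators, 10 of 14 measured genes had the higher CPM in the library labelled DKO and 4 the lower (median 0.24, percentile 99.6). Lrp1 and Lrp5, which encode receptors of the lipoprotein receptor family, had ratios of 1.30 (1.22 to 1.39) and 1.62 (1.20 to 2.20), and Scarb1, the HDL receptor SR-BI, 1.21 (1.08 to 1.36). The epsins and clathrin adaptors split into 12 higher and 5 lower (median 0.06, percentile 78.2). Ap2a2, a subunit of the AP-2 adaptor, was at 1.31 (1.14 to 1.51), Picalm at 0.759 (0.696 to 0.827) and the clathrin heavy chain Cltc at 0.844 (0.779 to 0.913). Of the cholesterol synthesis genes 17 were higher and 6 lower (median 0.08, percentile 93.7). Lss, the lanosterol synthase, was at 1.46 (1.12 to 1.90), Stard4 at 1.22 (1.11 to 1.34), Hmgcs1 at 1.15 (1.09 to 1.22) and Sc5d at 0.915 (0.873 to 0.960). Fatty acid and triglyceride synthesis showed 16 genes higher and 7 lower (median 0.06, percentile 93.4). The desaturases Fads1 and Fads2 had ratios of 1.20 (1.13 to 1.28) and 1.26 (1.19 to 1.33). Dgat2, which completes triglycerides, was at 1.18 (1.13 to 1.23), and Scd1, the stearoyl-CoA desaturase, at 0.815 (0.793 to 0.837).

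Apolipoproteins and genes of lipoprotein assembly were lower in 14 of 21 cases (median -0.15, percentile 6.54), but the list apolipoproteins and lipoprotein assembly stood at 0.15 in clusters 5, 7 and 8 alone. Apoh, Apom and Apoa2 had ratios of 0.642 (0.627 to 0.657), 0.642 (0.612 to 0.673) and 0.724 (0.719 to 0.729). By contrast, Apoa4, which leads cluster 7, was at 1.88 (1.73 to 2.04). Fatty acid oxidation and ketogenesis was even, with 12 genes higher and 12 lower (median -0.02, percentile 66.5). Decr1 stood at 0.728 (0.673 to 0.788), Acaa2 at 0.786 (0.759 to 0.813), Cyp4a14 at 0.793 (0.765 to 0.823) and Ppara, the fatty acid sensor of the liver, at 1.27 (1.21 to 1.33). Among bile acid genes 13 of 18 were lower (median -0.03, percentile 58.5). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.750 (0.699 to 0.805) and Cyp7b1 at 0.733 (0.660 to 0.814). Glycogen genes showed 6 higher and 10 lower (median -0.07, percentile 29.5), with Stbd1 at 1.37 (1.14 to 1.64) and Ugp2 at 0.861 (0.826 to 0.897). Of the hepatocyte transcription factors 13 were higher and 7 lower (median 0.09, percentile 96.5), with the list at -0.05 in clusters 5, 7 and 8 alone. Cebpa was at 1.41 (1.27 to 1.56) and Hnf4a at 1.26 (1.19 to 1.34). Alb, the albumin gene, was at 0.852 (0.848 to 0.856).

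The unfolded protein response list had 10 genes higher and 5 lower (median 0.15, percentile 98.0). The endoplasmic reticulum chaperones Pdia4 and Hyou1 stood at 1.76 (1.58 to 1.95) and 1.51 (1.29 to 1.78), Hspa5 at 1.13 (1.08 to 1.19) and Manf at 0.781 (0.701 to 0.869). Interferon-stimulated genes were higher in 10 of 17 cases (median 0.15, percentile 93.4), with Ifit1 at 1.85 (1.37 to 2.53) and Stat2 at 1.29 (1.12 to 1.48). Mitochondrially encoded transcripts were higher in 12 of 13 cases (median 0.74, percentile 100; 0.14 in clusters 5, 7 and 8 alone), with mt-Nd2 at 2.54 (2.502 to 2.57) and mt-Cytb at 2.07 (2.04 to 2.10). Nuclear-encoded genes of oxidative phosphorylation were lower in 16 of 20 (median -0.20, percentile 1.67), and the list oxidative phosphorylation, nuclear encoded, stood at -0.03 in the same clusters. Cox4i1 was at 0.610 (0.592 to 0.629), Cox5a at 0.657 (0.630 to 0.685) and Ndufa4 at 0.666 (0.648 to 0.684). Pericentral, periportal, acute phase and gluconeogenesis genes had medians of -0.05, 0.03, -0.03 and -0.06 at percentiles 49.9, 87.6, 64.8 and 48.8. The median over all genes of the class was 0.00.

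The genes highest by the fixed rank in the library labelled DKO, given in order of ratio as are those below, included the major urinary protein gene Mup9 (ratio 4.31, 3.49 to 5.37), Dnajc12 (3.77, 3.35 to 4.26), Cdk8 (3.74, 3.54 to 3.96) and Cmss1 (3.44, 3.36 to 3.51). Next came Apba3 (2.55, 1.69 to 3.93), Il31ra (2.46, 2.18 to 2.79), Cdk2ap1 (2.41, 1.67 to 3.53), Lars2 (2.04, 1.96 to 2.12) and Apoa4. Cmss1, Cdk8 and Lars2 lead cluster 2 together with Gm42418, an annotated transcript over ribosomal RNA sequence. Gm42418 took 39506 against 23354 CPM in hepatocytes, 111756 against 29639.7 CPM in other liver cells and 60291 against 29679 CPM over all aorta cells. Those lowest were Reg1 (0.105, 0.0487 to 0.202), Clps (0.1503, 0.0971 to 0.225), Prss2 (0.167, 0.108 to 0.249), Ccdc152 (0.186, 0.175 to 0.197) and Ctrb1 (0.209, 0.155 to 0.278). They were followed by Ulk4 (0.212, 0.144 to 0.304), Cela3b (0.217, 0.127 to 0.356), Pnlip (0.239, 0.141 to 0.389), the sulfotransferase Sult2a6 (0.300, 0.238 to 0.377) and AY036118 (0.334, 0.327 to 0.342). Reg1, Clps, Prss2, Ctrb1, Cela3b and Pnlip are pancreatic acinar genes that liver cells are not known to use. Most of them lead cluster 16, which holds 40 cells labelled DKO and 6 labelled WT. Median depth there was 840 UMIs per cell labelled DKO and 3086.5 per cell labelled WT. Sums of UMIs give such deeper cells more weight, so few cells may carry much of these ratios. Different clusters hold most of the class. They are clusters 2, 7, 0, 5 and 8 in the library labelled DKO (791, 462, 427, 406 and 327 cells). In that labelled WT they are clusters 3, 1, 0, 2 and 6 (663, 643, 603, 479 and 410). In clusters 5, 7 and 8 alone the log2 ratio of Alb was 0.01 against -0.23 in the class. With every cell weighted alike, the interferon list stood at -0.04 and the acinar genes moved toward 0, such as Pnlip at -1.06 from -2.07.

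**Figure D2:**
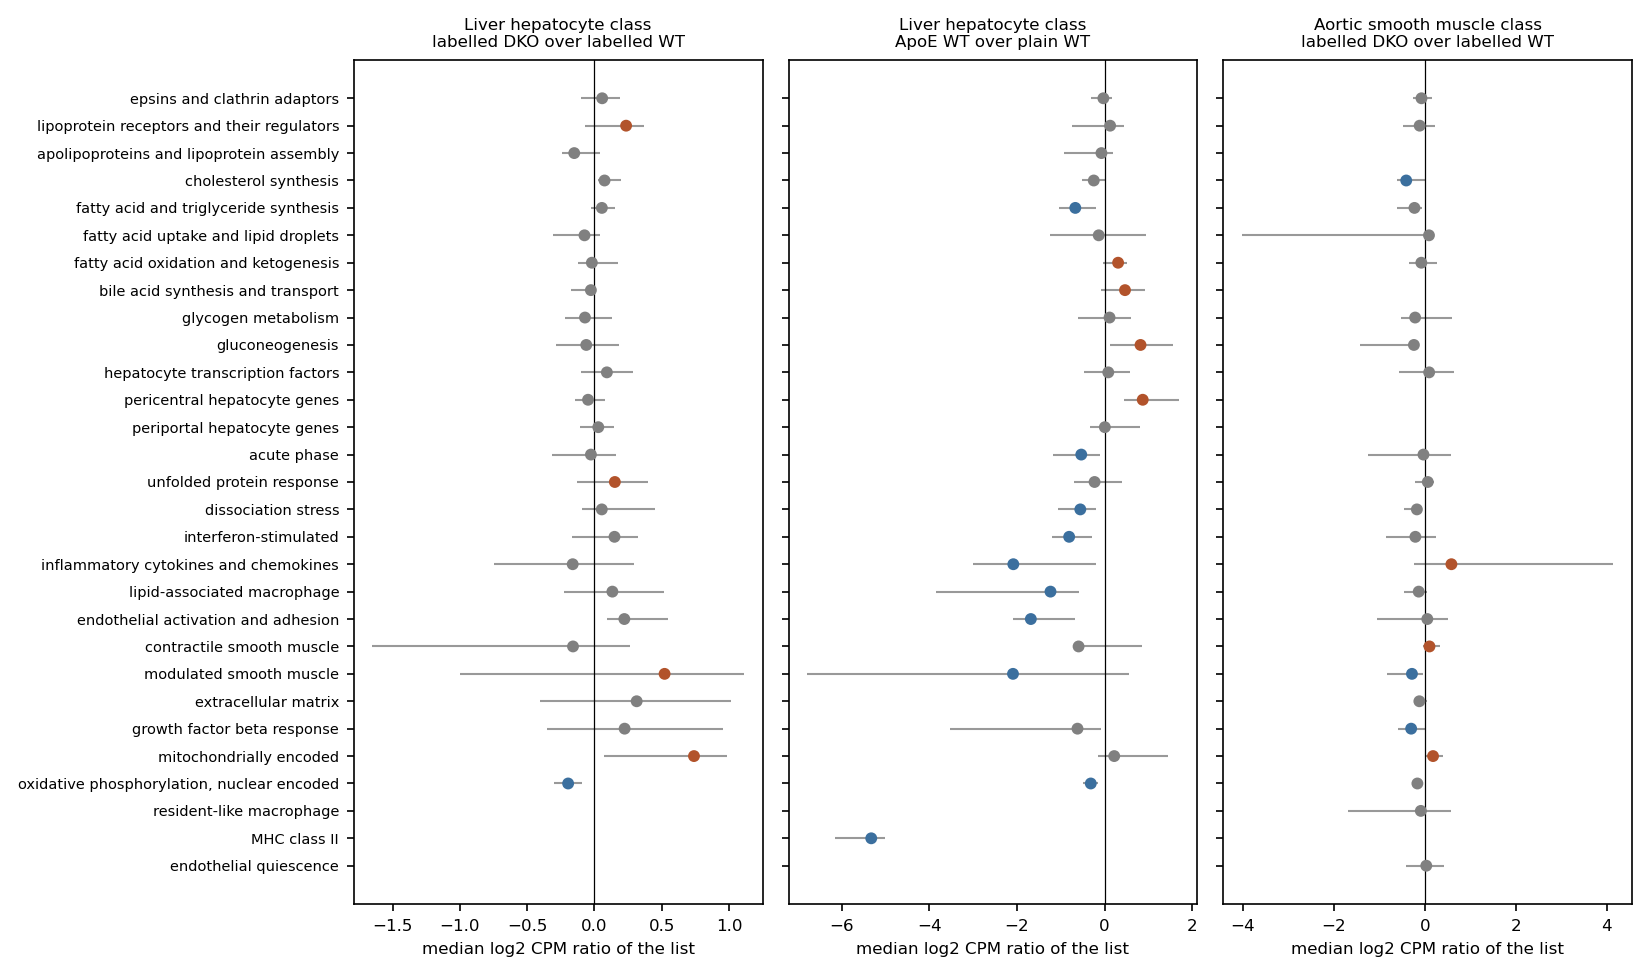
Median log2 CPM ratio of each gene list (x axis, log2 scale) in hepatocytes labelled DKO over WT, hepatocytes labelled WT on the ApoE background over WT without it, and aortic smooth muscle labelled DKO over WT; bars are 95% order-statistic intervals of the median over list members, which are not replicates, and colour marks lists at or beyond the highest (orange) or lowest (blue) 2.5% of random lists. In the hepatocyte panel of DKO over WT the mitochondrially encoded list lies at 0.74 and the nuclear oxidative phosphorylation list at -0.20; in smooth muscle the contractile list lies at 0.10 and the modulated list at -0.28.

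In hepatocyte clusters 5 and 7, genes of the opposite liver zone were lower in the library labelled DKO. Hepatocyte genes were also lower there in cells of other types, such as Alb in T cells (ratio 0.482), and free RNA was not measured. In cluster 5, led by the pericentral genes Glul, Oat and Cyp1a2, periportal genes were lower in 12 of 15 cases (median -0.47, percentile 0). Cyp2f2 was at 0.362 (0.256 to 0.506), Gls2 at 0.492 (0.350 to 0.686) and Cps1, which starts the urea cycle, at 0.763 (0.730 to 0.798). Interferon-stimulated genes were higher in 8 of 12 (median 0.44, percentile 99.7), with Bst2 at 1.46 (1.08 to 1.99) and Stat2 at 1.38 (0.928 to 2.09). Acute phase and gluconeogenesis genes had medians of -0.17 and -0.22 (percentiles 1.02 and 1.79). Dnajc12 (3.37, 2.71 to 4.22), Mup18 (3.05, 2.36 to 3.98), Mup16 (2.76, 1.95 to 3.98) and Nfe2l1 (2.38, 1.79 to 3.18) were the highest by rank. Cyp2f2, Ccdc152 (0.409, 0.341 to 0.488) and Cyp3a44 (0.583, 0.5003 to 0.679) were among the lowest. Mup genes are near copies of one another, so their UMIs can be assigned to the wrong member.

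In cluster 7, led by periportal genes such as Cyp2f2 and Gls2, pericentral genes were the lower ones (13 of 15, median -0.55, percentile 0). Oat was at 0.337 (0.253 to 0.446), Cyp2e1 at 0.451 (0.400 to 0.508) and Lect2 at 0.4996 (0.383 to 0.651). Acute phase genes were higher in 15 of 21 (median 0.20, percentile 100). The serum amyloid genes Saa2 and Saa1 stood at 5.68 (3.68 to 9.22) and 2.68 (2.05 to 3.56), Hp, which encodes haptoglobin, at 1.52 (1.41 to 1.63) and Fga at 1.25 (1.18 to 1.32). Cholesterol synthesis was higher in 15 of 22 (median 0.22, percentile 99.9). Idi1 was at 1.45 (1.19 to 1.78), Cyp51 at 1.51 (1.19 to 1.94) and Fdps at 1.32 (1.04 to 1.70). Lipoprotein receptors and regulators were higher in 9 of 11 (median 0.34, percentile 99.2), with Commd1 at 1.62 (1.05 to 2.59) and Scarb1 at 1.26 (0.955 to 1.69). Mup9 (21.6, 9.10 to 67.0, 231 against 5 UMIs), Il31ra (5.75, 3.69 to 9.46), Cdk8 (4.54, 3.69 to 5.64) and Cmss1 (4.13, 3.74 to 4.57) ranked highest. Mup17 (0.266, 0.223 to 0.316), Ccdc152 (0.398, 0.348 to 0.454) and Cyp2e1 ranked among the lowest. The glycogen list had a median of -0.21 and that of oxidative phosphorylation 0.10 (percentiles 2.32 and 97.7).

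Cluster 8 had periportal genes lower in 15 of 17 cases (median -0.38, percentile 0), with Etnppl at 0.394 (0.286 to 0.539), Cyp2f2 at 0.460 (0.377 to 0.560) and Hsd17b6 at 0.491 (0.391 to 0.614). Pericentral genes were higher in 10 of 16 (median 0.16, percentile 99.9), with Cyp2a5 at 1.71 (1.54 to 1.90) and Cyp2e1 at 1.28 (1.23 to 1.34). Lipoprotein receptors and regulators were higher in 11 of 12 (median 0.18, percentile 97.6), with Lrp1 at 1.32 (1.14 to 1.52) and Scarb1 at 1.16 (0.883 to 1.53). Genes linked to dissociation stress were higher in 10 of 17 (median 0.16, percentile 99.6), including Fos at 1.47 (1.21 to 1.79) and Jun at 1.37 (1.20 to 1.58). Cmss1 (3.54, 3.26 to 3.85), Cdk8 (3.29, 2.80 to 3.88), Dnajc12 (3.24, 2.5001 to 4.25) and Camk1d (2.33, 2.16 to 2.51) ranked highest. Ccdc152 (0.184, 0.157 to 0.214), AY036118 (0.353, 0.321 to 0.387), Etnppl and Cyp2f2 ranked lowest.

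In T cells of cluster 9 (386 against 86 cells), the early-response genes Klf2 and Klf6 were higher in the library labelled DKO, at 3.37 (2.42 to 4.80) and 2.06 (1.26 to 3.54). They belong to a dissociation stress list with 8 higher and 6 lower genes (median 0.44, percentile 99.2). Cmss1 (8.62, 7.74 to 9.62), Cdk8 (6.76, 5.11 to 9.14) and Camk1d (4.04, 3.67 to 4.45) ranked among the highest. The lowest were C8g (0.283, 0.230 to 0.349), Mt1 (0.284, 0.231 to 0.349), Mup17 (0.295, 0.251 to 0.346) and Ifitm3 (0.303, 0.249 to 0.370). Hepatocyte genes were lower there as well. Alb was at 0.482 (0.466 to 0.498), and apolipoproteins were lower in 16 of 17 cases (median -0.94, percentile 0). Kupffer cells had the same contrast, with Cdk8 (8.27, 5.83 to 12.1), Cmss1 (7.79, 6.85 to 8.90), Lars2 (4.53, 3.44 to 6.08) and Camk1d (3.82, 3.41 to 4.27) highest. The hepatocyte genes Mup17 (0.261, 0.206 to 0.330), Ttr (0.316, 0.289 to 0.346), Mup3 (0.345, 0.307 to 0.389) and Apoa2 (0.364, 0.342 to 0.389) were lowest, and apolipoproteins were lower in 17 of 18 (median -1.11, percentile 0.0200). In endothelial cells Cdk8 (9.86, 6.30 to 16.2), Cmss1 (5.61, 4.90 to 6.45), Camk1d (3.60, 3.20 to 4.06) and Gphn (2.81, 2.15 to 3.71) were highest. Mup17 (0.301, 0.226 to 0.396), Cyb5a (0.322, 0.259 to 0.399), Ang (0.318, 0.225 to 0.442) and Ddt (0.322, 0.228 to 0.447) were lowest. Mitochondrially encoded transcripts were higher in 11 of 12 cases (median 1.08, percentile 100) and pericentral genes lower in 12 of 13 (median -1.20, percentile 0). The median over all genes in endothelial cells was -0.12.

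Hepatocytes of the 2 liver libraries labelled WT were compared as well (4021 cells of the library whose label names an ApoE background and 261 of the one whose label names none). Ratios here are the former over the latter, and no difference is assigned to the ApoE genotype. Genes of glucose output and of pericentral hepatocytes were higher in the library labelled ApoE, and genes of fatty acid synthesis, the acute phase and inflammation were lower. Other cell types were set apart only in the library labelled ApoE, since the authors call all cells of the other library hepatocytes. Immune cells or their RNA may thus remain in the class of that other library, which limits the inflammation lists. Of the gluconeogenesis genes 11 of 13 were higher (median 0.82, percentile 100). G6pc, the glucose-6-phosphatase, was at 5.35 (4.54 to 6.34), Pck1 at 3.58 (3.31 to 3.87), Tat at 2.97 (2.69 to 3.30) and Foxo1 at 2.81 (2.16 to 3.73). Fatty acid and triglyceride synthesis was lower in 17 of 23 cases (median -0.67, percentile 0). Scd1 stood at 0.101 (0.0989 to 0.104), Acss2 at 0.316 (0.272 to 0.368) and Elovl6 at 0.338 (0.298 to 0.386), while Lpin1 went the other way at 11.2 (8.93 to 14.3). Apoe was at 0.526 (0.399 to 0.702), Epn1 at 1.26 (0.922 to 1.77) and Epn2 at 0.981 (0.451 to 2.53).

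Pericentral genes were higher in 15 of 18 cases (median 0.87, percentile 100), including Cyp2c50 at 7.37 (5.72 to 9.68), Cyp2e1 at 5.71 (5.19 to 6.29) and Cyp1a2 at 3.73 (3.04 to 4.61). Bile acid synthesis and transport was higher in 13 of 18 (median 0.47, percentile 99.9), with the sterol exporter Abcg8 at 3.796 (2.49 to 6.09) and Cyp27a1 at 2.93 (2.19 to 4.02). Fatty acid oxidation was higher in 17 of 24 (median 0.31, percentile 98.7), with Cyp4a14 at 3.93 (3.37 to 4.61) and Cyp4a10 at 1.86 (1.59 to 2.18). Acute phase genes were lower in 17 of 22 cases (median -0.53, percentile 0), with Saa1 at 0.147 (0.130 to 0.165), Saa2 at 0.143 (0.122 to 0.167) and Orm2 at 0.254 (0.201 to 0.324). Interferon-stimulated genes were lower in 14 of 17 (median -0.81, percentile 0.145) and dissociation stress genes in 13 of 17 (median -0.55, percentile 0.180). Cytokines and chemokines were lower in 8 of 9 (median -2.08, percentile 0) and genes of lipid-associated macrophages in 12 of 13 (median -1.23, percentile 0). All 4 measured MHC class II genes, which hepatocytes are not known to use at high levels, were lower (median -5.33, percentile 0). Clusters of immune cells were set apart only in the library labelled ApoE, so these immune lists do not describe hepatocytes alone. Apolipoproteins, cholesterol synthesis and lipoprotein receptors had medians of -0.07, -0.25 and 0.13 (percentiles 24.6, 8.43 and 84.9).

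The 10 highest by rank were, in order of ratio, Mup11 (122, 33.8 to 1009, 2384 against 2 UMIs), Cyp2c54 (70.8, 24.2 to 344), the organic anion transporter Slco1a1 (748 against 0 UMIs, at least 25.6-fold higher) and Sult3a1 (17.5, 10.6 to 31.3). Next were Zbtb16 (14.8, 9.58 to 24.3), Cyp3a44 (14.4, 9.11 to 24.4), Sult2a8 (14.1, 9.67 to 21.4), Lpin1 and Cyp2c37 (10.0, 7.07 to 14.7). The acinar gene Ctrb1 came last (274 against 0 UMIs, 9.36-fold against the same floor). The lowest, in the same order, were Spp1, which encodes osteopontin (0.00904, 0.00525 to 0.0147), Mup20 (0.0296, 0.0275 to 0.0318), Sult1e1 (0.0678, 0.0459 to 0.0994), Lcn2 (0.0788, 0.0694 to 0.0895) and Apoa4 (0.0830, 0.0758 to 0.0909). They were followed by Gstm3 (0.0853, 0.0714 to 0.102), Klf6 (0.0919, 0.0620 to 0.136), Gdf15 (0.0969, 0.0773 to 0.121), Scd1 and Anxa5 (0.118, 0.101 to 0.137). Spp1 also leads cluster 0 of the liver without the ApoE background, which was kept out of the class. The libraries lie in separate tables and the median over all common genes was -0.09. With cells thinned to 1000 UMIs the cholesterol synthesis list stood at 0.13 in place of -0.25.

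**Figure D3:**
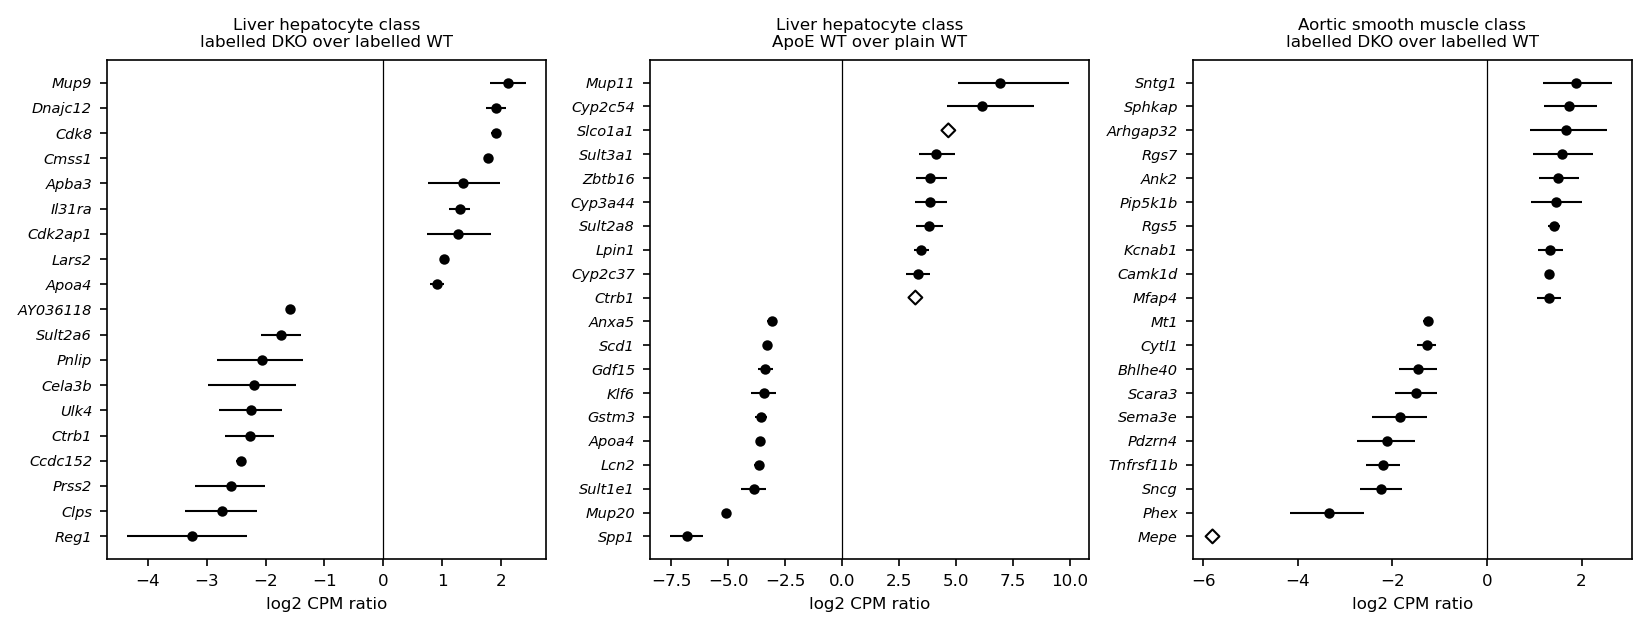
Log2 CPM ratio (x axis) of the highest and lowest ranked genes described, in hepatocytes labelled DKO over WT, hepatocytes labelled WT on the ApoE background over WT without it, and aortic smooth muscle labelled DKO over WT; points are ratios, bars exact 95% intervals for counting error, and open diamonds mark genes with no UMI in one library, placed at the floor of 3 counts. By plotted point, the largest difference in each panel is Reg1 at a ratio of 0.105, Mup11 at 122 and Mepe with 0 against 110 UMIs.

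In the aorta, smooth muscle cells took 36.9% (35.1 to 38.7) of the cells labelled DKO and 22.7% (21.2 to 24.3) of those labelled WT, a ratio of 1.63 (1.47 to 1.80). Most of the surplus lies in cluster VS3, with 351 against 72 cells. This cluster is led by Gm42418 and Camk1d, with no smooth muscle marker among its leading genes and a median of 596 UMIs per cell labelled DKO. Clusters VS1 and VS2 had 357 against 338 and 326 against 226 cells. B cells were fewer in the library labelled DKO (14 against 85 cells, ratio 0.165 (0.0864 to 0.292)). Erythroid cells were 7.43% against 4.93% (ratio 1.51, 1.21 to 1.88), but 0.754 (0.465 to 1.21) in place of that ratio under the stricter filter on cells. Sizes of the authors' fibroblast, stem cell, adipocyte, endothelial and macrophage clusters are not interpreted, a choice that followed no fixed limit. Smooth muscle did not pass a check that these failed. Gm42418, which leads VS2 and VS3, had a ratio of 2.12 between the libraries in smooth muscle, which limits that share as well. For endothelial cells (50 against 84) the share ratio was 0.595 (0.411 to 0.855). It was 0.677 under the stricter filter on cells and 0.469 with clusters made here. Over 70% of the cells come from 1 library in VS3, HS1, HS3, HS4, TC4 and the B cells of the aorta and in liver clusters 3, 6, 9 (T cells), 11, 14, 15 (neutrophils), 16 and 18, and with 1 library per group a cell type cannot be separated from a library there.

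Smooth muscle labelled DKO had lower genes of modulated smooth muscle, the state in which these cells lose contractile proteins and take on matrix or cartilage genes. Contractile genes were somewhat higher in summed UMIs but not with every cell weighted alike. In the smooth muscle class (1034 against 636 cells), 13 of 18 contractile genes were higher (median 0.10, percentile 99.2), and with every cell weighted alike the contractile list stood at -0.01. Actg2 was at 1.71 (1.36 to 2.18), Mylk, the myosin light chain kinase, at 1.36 (1.26 to 1.48), Synpo2 at 1.30 (1.17 to 1.44) and Cnn1, which also leads VS1 and VS2, at 1.26 (1.16 to 1.36). Modulated smooth muscle genes were lower in 14 of 18 cases (median -0.28, percentile 0.630). Tnfrsf11b, which encodes osteoprotegerin, stood at 0.219 (0.171 to 0.279), Sox9, a master regulator of cartilage, at 0.344 (0.233 to 0.501), Spp1 at 0.561 (0.521 to 0.604) and Dcn at 0.613 (0.557 to 0.674). Tnfrsf11b and Spp1 also lead cluster FB1, which holds 221 cells labelled DKO and 402 labelled WT, and free RNA of such cells was not measured. Genes of the transforming growth factor beta response were lower in 10 of 12 (median -0.30, percentile 1.68). Ccn2 was at 0.685 (0.648 to 0.723), Skil at 0.703 (0.601 to 0.822), Tgfb1 at 0.668 (0.512 to 0.872) and Smad7 at 0.780 (0.659 to 0.925).

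Cholesterol synthesis genes were lower in 11 of 17 cases (median -0.41, percentile 1.45). Only Insig1, at 0.754 (0.515 to 1.11), and Hmgcs1, at 1.01 (0.775 to 1.31), had 100 UMIs or more. Mitochondrially encoded transcripts were higher in 12 of 13 (median 0.18, percentile 99.8), with mt-Nd3 at 1.77 (1.52 to 2.06), and Gm42418 stood at 88398 against 41688 CPM. Cytokines and chemokines were higher in 4 of 6 (median 0.59, percentile 99.7), with Cxcl2 at 1.58 (1.19 to 2.12) and Cxcl1 at 1.43 (1.07 to 1.92). Extracellular matrix genes were split, 9 higher and 16 lower (median -0.12, percentile 31.4), with Postn at 1.94 (1.73 to 2.17), Timp3 at 0.711 (0.656 to 0.770) and Sparc at 0.760 (0.722 to 0.799). Dissociation stress genes were lower in 19 of 21 (median -0.17, percentile 11.1). Epsins and clathrin adaptors had a median of -0.07 (percentile 55.4), with the median over all genes at -0.08.

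The 10 highest ranked genes in smooth muscle were, in order of ratio, Sntg1 (3.68, 2.27 to 6.25), Sphkap (3.34, 2.30 to 4.98), Arhgap32 (3.21, 1.89 to 5.77), Rgs7 (2.99, 1.96 to 4.72) and Ank2 (2.85, 2.14 to 3.85). Next were Pip5k1b (2.75, 1.91 to 4.05), Rgs5 (2.68, 2.45 to 2.94), the potassium channel subunit Kcnab1 (2.54, 2.11 to 3.07), Camk1d (2.499, 2.34 to 2.67) and Mfap4 (2.49, 2.10 to 2.96). Rgs5 also leads VS1 and VS2, and Camk1d leads VS3. The lowest, in the same order, were Mepe (0 against 110 UMIs) and Phex (0.0988, 0.0556 to 0.165), both genes of mineralizing tissue. They were followed by Sncg (0.213, 0.156 to 0.287), Tnfrsf11b, Pdzrn4 (0.231, 0.149 to 0.349), Sema3e (0.281, 0.187 to 0.415), Scara3 (0.354, 0.260 to 0.478), Bhlhe40 (0.365, 0.274 to 0.482), Cytl1 (0.413, 0.359 to 0.474) and the metallothionein Mt1 (0.423, 0.392 to 0.457). With every cell weighted alike the extracellular matrix list stood at 0.05 in place of -0.12.

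In the authors' fibroblast cluster FB1, contractile genes were higher in the library labelled DKO in 16 of 17 cases (median 1.21, percentile 100), with Cnn1 at 3.43 (2.78 to 4.25) and Myh11 at 2.98 (2.67 to 3.34). Kcnab1 (5.57, 3.62 to 8.80), Sost (4.86, 3.33 to 7.22) and Rgs5 (4.18, 3.41 to 5.15) ranked with them. Cnn1, Myh11, Sost and Rgs5 also lead VS1 and VS2, of which free RNA was not measured. Ibsp, which encodes bone sialoprotein, had 22 against 2490 UMIs, Chil1 3 against 326 UMIs and Dmp1 0 against 114 UMIs. The cluster carries more chondrocyte-like than fibroblast markers, and acute phase genes were lower in 9 of 10 (median -1.28, percentile 0). In cluster HS3, which the authors call stem cells and whose leading genes are those of cartilage, Alpl, the tissue-nonspecific alkaline phosphatase, had 0 against 122 UMIs and Col10a1, a collagen of hypertrophic cartilage, 0 against 130 UMIs. Csmd1 (36.3, 17.7 to 86.7, 93 against 8 UMIs), Thbs1 (5.51, 3.65 to 8.44), Stard13 (4.49, 3.06 to 6.64) and Ripk2 (4.17, 2.79 to 6.28) were higher there, as were contractile genes in 16 of 17 cases (median 0.90, percentile 100). Ibsp leads HS3, which holds 96 cells labelled DKO and 257 labelled WT and whose free RNA was not measured. It was also lower in the endothelial cluster (1 against 111 UMIs), in AP2 (4 against 314 UMIs) and in HS2 (5 against 210 UMIs).

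In HS2, contractile genes were higher in 16 of 17 cases (median 0.51, percentile 100). Dissociation stress genes were lower in 20 of 21 (median -0.48, percentile 0), with Hspa1a, a heat shock protein gene, at 0.437 (0.333 to 0.569) and Fos at 0.640 (0.588 to 0.696). Saa3 (5.49, 3.65 to 8.53), Col8a1 (5.49, 4.22 to 7.23), Rgs5 (4.87, 3.82 to 6.26) and Csmd1 (4.26, 3.09 to 5.98) ranked highest and Chil1 (0.00457, 0.000552 to 0.0166, 2 against 431 UMIs) lowest. In HS1, with 254 against 75 cells and an all-gene median of 0.10, modulated smooth muscle genes were lower in 14 of 16 (median -0.67, percentile 0.0300). Dtna (5.39, 2.55 to 13.6), Hdac5 (5.01, 2.37 to 12.7) and Insr, the insulin receptor (4.95, 2.21 to 13.8), ranked highest there, and Prg4 (0.0221, 0.0124 to 0.0370), Bmp2 (0.0425, 0.0228 to 0.0740) and Ank (0.0939, 0.0762 to 0.115) lowest. Rgs5 leads VS1 and VS2, Prg4 leads HS3 and Bmp2 leads FB1. Free RNA of those clusters was not measured.

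The clusters that the authors call adipocytes, AP1 and AP2, carry fibroblast markers and no adipocyte marker among their leading genes. Unfolded protein response genes were higher in the library labelled DKO in 13 of 13 cases in AP1 (median 0.61, percentile 100) and 11 of 12 in AP2 (median 0.42, percentile 99.9). Manf was at 2.45 (1.98 to 3.06) and 1.67 (1.19 to 2.36) and Herpud1 at 1.53 (1.21 to 1.94) and 1.74 (1.17 to 2.61). In AP1, cytokines and chemokines were higher in 5 of 7 (median 0.73, percentile 100) and contractile genes lower in 15 of 16 (median -0.36, percentile 0.120). Txnip (2.71, 2.22 to 3.33), Fibin (2.29, 1.75 to 3.03) and Tsc22d3 (2.22, 1.79 to 2.76) were highest and Erbb4 (0.0838, 0.0470 to 0.140), Spp1 (0.236, 0.201 to 0.277) and Scin (0.284, 0.180 to 0.434) among the lowest. In AP2, Lcn2 (5.18, 3.41 to 8.15), Tgfbi (2.62, 1.75 to 4.001), Camk1d (2.23, 1.97 to 2.52) and Mmp3 (2.22, 1.73 to 2.87) were highest and Hp (1 against 103 UMIs), Mmp13 (1 against 101 UMIs) and Ecrg4 (0.206, 0.137 to 0.301) lowest. Spp1 and Ecrg4 lead FB1, while Lcn2, Hp and Mmp13 lead HS2, and free RNA of those clusters was not measured.

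In the macrophage cluster MP1 (82 against 118 cells, all-gene median -0.15), genes of resident-like macrophages were lower in 7 of 7 cases (median -1.37, percentile 0). MHC class II genes were lower in 5 of 5 (median -0.65, percentile 0.835), with H2-Aa at 0.441 (0.314 to 0.609) (log2 0.15 with cells thinned to 1000 UMIs, against -1.18). With cells thinned, the MHC class II list in MP1 stood at -0.22, and under the stricter filter on cells it stood at -0.11 and H2-Eb1 at log2 0.14 against -0.52. Fn1 (4.26, 3.52 to 5.16), the lysosomal protease gene Ctsl (3.25, 2.51 to 4.23) and Camk1d (2.68, 2.27 to 3.18) ranked highest in MP1 and Penk (0 against 262 UMIs), Ecrg4 (0.102, 0.0402 to 0.217), Selenop (0.388, 0.245 to 0.593) and Lum (0.434, 0.312 to 0.592) lowest. Penk and Ecrg4 lead cluster FB1, whose free RNA was not measured. In MP2 (57 against 55 cells), MHC class II genes were higher in 5 of 5 (median 1.64, percentile 99.9), with H2-Aa at 11.5 (6.28 to 23.4) and Cd74 at 3.12 (2.55 to 3.85). Resident-like genes were higher in 4 of 5 (median 2.32, percentile 100) and contractile genes in 12 of 13 (median 1.41, percentile 100). Itga8 (7.09, 3.59 to 15.97), Csrp2 (6.86, 4.16 to 12.04) and Lyz2 (5.66, 3.94 to 8.39) ranked with H2-Aa. Contractile genes such as Acta2 and Myh11 lead VS1 and VS2, and free RNA of smooth muscle was not measured. Gdf15 (0.220, 0.135 to 0.347), Hmox1 (0.256, 0.192 to 0.337), Zfp36l2 (0.290, 0.192 to 0.433) and Atf3 (0.310, 0.242 to 0.395) were lowest.

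In endothelial cells (50 against 84), activation and adhesion genes were higher in the library labelled DKO in 9 of 11 cases (median 0.53, percentile 99.2). Quiescence genes were higher in 8 of 10 (median 0.42, percentile 97.7), and contractile genes lower in 16 of 16 (median -0.51, percentile 0). Fabp4, a fatty acid carrier of capillary endothelium, was at 12.1 (7.84 to 19.7), Ramp2 at 3.68 (2.46 to 5.65) and Rgs5 at 3.58 (2.34 to 5.63). Cdk11b (0.189, 0.101 to 0.329), Akap12 (0.204, 0.111 to 0.350) and Igfbp4 (0.235, 0.143 to 0.371) were lowest. In the T cell cluster TC1 (62 against 83 cells), acute phase genes were lower in 7 of 7 (median -1.56, percentile 0). Plxdc2 (5.16, 3.07 to 9.13), Odc1 (4.38, 2.71 to 7.34), Inpp4b (4.27, 2.65 to 7.18) and Pard3 (2.73, 2.14 to 3.50) were highest. Aebp1 (0.224, 0.136 to 0.352), Clu (0.258, 0.188 to 0.349) and Wls (0.286, 0.189 to 0.422), which fibroblasts also use, were among the lowest. Rgs5 leads VS1 and VS2 and Clu leads FB1, and free RNA of those clusters was not measured.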

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

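Alternatives that use clusters 5, 7 and 8 alone, cluster VS1 alone, all of the authors' hepatocytes, the hepatocyte class without clusters 6 and 16, or totals without genes linked to ribosomal RNA were chosen after the results were seen. Of 6598 alternative values for 862 results, 5959 stayed within the interval of the result (over list members for lists, counting error otherwise), 625 moved outside it and 14 turned the direction of a result whose interval excluded a ratio of 1. Other changes of sign are among the first 2 counts. No paired analysis was possible because the groups share only 1 replicate number. Removal of doublets was not run, since the caller marked almost none. Lists and genes without UMIs under an alternative have no value there. Thinning cells to 1000 UMIs, which also left out cells with fewer, moved 208 of 851 results; depth and the set of cells differ together there. Values below are log2 ratios, with shares as ratios, DKO over WT unless the liver background is named; the cause was not tested for any of them.

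With thinned cells, values were 0.0268 for Ppp1r3c (from -0.42) and 1.04 for mitochondrially encoded genes in hepatocytes, 0.0524 for the latter in Kupffer cells (from -0.22), 0.15 for H2-Aa in MP1, -0.23 for fatty acid oxidation and ketogenesis in AP1 (from 0.12), 0.13 for cholesterol synthesis in the liver background comparison, and for the list oxidative phosphorylation, nuclear encoded, -0.35 in smooth muscle, -0.12 in FB1 and -0.0324 in TC1 (from -0.16, 0.16 and 0.16). With the mean of each cell's CPM they were -0.24 for apolipoproteins and lipoprotein assembly, 0.20 for mitochondrially encoded genes in Kupffer cells, 0.0118 for dissociation stress in MP1 (from -0.47), 0.0505 for extracellular matrix in smooth muscle, and -0.26 and -0.15 for mitochondrially encoded and nuclear oxidative phosphorylation genes in the background comparison (from 0.22 and -0.32). The stricter filter on cells gave 0.14 for H2-Eb1 in MP1 and share ratios of 1.32 for Kupffer cells and 0.636 and 0.754 for erythroid cells of liver and aorta. Clusters 5, 7 and 8 gave 0.0133 for Alb, 0.15 for apolipoproteins, -0.0355 for fatty acid and triglyceride synthesis and -0.0308 for oxidative phosphorylation. All of the authors' hepatocytes gave -0.50 for Apoe and -0.0724 for the growth factor beta response list in the background comparison. Clusters made here gave share ratios of 0.227 for hepatocytes and 2.02 for smooth muscle. Members from 1 UMI gave -0.20 for modulated smooth muscle genes in hepatocyte cluster 7 (from 1.52) and 0.0148 for resident-like macrophage genes in AP2. Cluster VS1 gave -0.23 for extracellular matrix, totals without mitochondrial and ribosomal protein genes 0.0367 for bile acid synthesis and transport, and oxidative phosphorylation in smooth muscle was -0.0859 with the median at 0 and -0.0843 without genes linked to ribosomal RNA.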

Other observations

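Genes of the transforming growth factor beta response, lower in smooth muscle labelled DKO, were also lower in the authors' fibroblast cluster FB1 and stem cell cluster HS1. They were lower in 10 of 12 cases in FB1 (median -0.48, percentile 0.320), with Skil at a ratio of 0.526 (0.425 to 0.647) and Ccn2 at 0.6002 (0.554 to 0.650), and in 10 of 11 in HS1 (median -0.49, percentile 1.39), with Tgfb2 at 0.469 (0.385 to 0.574) and Tgfb1 at 0.438 (0.325 to 0.596). In FB1 the cytokine and chemokine list was higher in 5 of 5 (median 0.80, percentile 99.8), with Cxcl2 at 2.36 (1.86 to 3.01) and Cxcl1 at 1.74 (1.44 to 2.10). Postn, which encodes the matrix protein periostin, was higher in FB1 (3.01, 2.57 to 3.53), HS3 (2.73, 2.15 to 3.48) and AP1 (1.84, 1.23 to 2.79), and the elastin gene Eln was at 1.95 (1.75 to 2.17) in FB1.

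Single genes of lipid droplets and glycogen differed between the liver libraries labelled WT, while both lists lay within the range of random lists. With the ApoE background over without it, the droplet coat gene Plin2 was at 0.425 (0.391 to 0.463), Hsd17b13 at 0.387 (0.347 to 0.432) and Plin5 at 3.72 (2.46 to 5.90) (list of fatty acid uptake and lipid droplets: 7 higher, 9 lower, median -0.13, percentile 23.8). Ppp1r3c, which directs a phosphatase to glycogen, stood at 5.12 (2.17 to 15.9) and the liver glycogen synthase Gys2 at 2.75 (2.12 to 3.63) (9 higher, 7 lower, median 0.11, percentile 82.0). In hepatocytes labelled DKO over WT, Fabp2 was at 0.640 (0.589 to 0.695) and G0s2, an inhibitor of triglyceride breakdown, at 0.662 (0.624 to 0.704) (5 higher, 11 lower, median -0.07, percentile 29.2).

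All tests below except those on the shallow hepatocyte clusters were chosen after the result was seen. The first pattern is that Epn1 and Epn2 were not lower in the liver library labelled DKO. The tables argue against Epn1 UMIs in hepatocytes being free RNA of other cell types, since Epn1 CPM outside the hepatocyte clusters was 0.705 times that in clusters 5, 7 and 8, with an upper bound of 0.958. Swapped labels stay open: the upper bound of the Epn1 ratio in clusters 5, 7 and 8, 1.38, was meant to argue against a swap, but it does not do so, because transcript ends can lie outside the deleted part in either library. UMIs from such ends stay open too, because the 443 Epn1 UMIs in clusters 5, 7 and 8 of the library labelled DKO are counts per gene and hold no exon; a genotype other than the label's was not tested.

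The second pattern is the higher level of Gm42418, Cmss1, Cdk8, Lars2, Camk1d and Gphn in the liver library labelled DKO. A technical shift of that library alone was not tested and stays open for all of them, because the aorta cannot show it. The tables argue against a technical shift of both libraries labelled DKO for Cdk8 and Cmss1, which were lower over all aorta cells labelled DKO (higher of their upper log2 bounds -0.22). For Gm42418, Camk1d and Lars2 such a shift cannot be told apart from a difference between genotypes, because their lowest log2 ratio in the aorta was 0.83 and label and library coincide; the median over a set of 6 genes of this kind was 0.0179. The pattern does not cover all genes linked to ribosomal RNA, since AY036118, which lies on the other strand within Gm42418, stood at log2 -1.58 in hepatocytes, -0.70 in endothelial cells, -0.09 in Kupffer cells and 0.11 in T cells of the liver, the last 2 with intervals that include 0. A change in hepatocytes alone, carried to other cells as free RNA, stays open: Gm42418 CPM outside the hepatocyte clusters was 7.05 times that in clusters 5, 7 and 8, and per hepatocyte marker UMI 1.69 times that in the highest hepatocyte cluster, but no empty droplets were used to measure the free RNA, and a difference made by the genotype was not tested.

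The third pattern is that hepatocyte clusters 0, 1, 2, 3 and 6 have far fewer UMIs per cell than clusters 5, 7 and 8. Nuclei or broken cells that kept nuclear RNA stay open, because 2 measures point in different directions. With the shallow clusters pooled, the nuclear transcript Malat1 stood at 0.323 times its level in clusters 5, 7 and 8 in the library labelled DKO. In that labelled WT it stood at 0.646 times. Such RNA would raise Malat1, but it was not compared cluster by cluster. Over cells of both libraries, the median mitochondrial share, which nuclei would lower, was 0.443% in cluster 2. It was at most 3.69% in clusters 0, 1, 3 and 6 and at least 14.3% in clusters 5, 7 and 8. In the library labelled DKO it reached 7.64% in cluster 3, against 13.3% in cluster 5, the lowest of clusters 5, 7 and 8. In that labelled WT it reached 3.34% in cluster 3, against 13.3% in cluster 8. Droplets that hold mainly free RNA cannot be excluded. The distance of the hepatocyte genes found in T and B cells to these clusters was 0.810 times that to clusters 5, 7 and 8 in the library labelled DKO (0.563 to 1.05) and 0.395 times in that labelled WT, and free RNA released mostly by such cells would give the same distance. No biological explanation was tested.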
